A study of Homo sapiens with 18 samples.

How the data were processed

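Polyadenylated RNA was sequenced from 2 human pancreatic ductal adenocarcinoma cell lines, PATU-8988T and PATU-8902, in 18 libraries that form 6 groups of 3. Each line received the vehicle DMSO for 24 h, or 2.5 µM DCLK1-IN-1, a small-molecule inhibitor of the doublecortin-like kinase DCLK1, for 6 h or 24 h. The series record describes biological triplicates, and the labels number the replicates 1 to 3. There was no DMSO group at 6 h, so the 6 h groups were compared with DMSO at 24 h. Per the labels' protocols, ERCC spike-in RNA was added to RNA normalised by cell count before a strand-specific library preparation and single-end sequencing.

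The authors deposited 1 table of FPKM values (fragments normalised to transcript length and scaled between libraries) with a row per gene symbol and a column per library. Per the submitters' processing notes, the tools were HISAT, Cufflinks and Cuffnorm and the build was hg19, with versions not given in the sources used here. The table held 26341 rows, of which 92 were spike-in controls and 26249 were genes. No value was 0. Each library had a floor between 0.0795 and 0.118 FPKM, shared by 6996 to 7001 rows (equal within 1e-06). The average log2 deviation of the 47 spike-in controls with a mean of at least 1 FPKM lay between -0.06 and 0.05 in each library. The summed FPKM of genes ran from 263339 to 764363, so libraries were level on the spike-ins and not on the library total. The table gave no counts, so the depth of each library is unknown and no counting interval is given. The table named genes without coordinates, and no position is printed. Whether counting used the strand is not given in the sources used here, so values of antisense genes (PAX8-AS1, ZNF337-AS1) cannot be separated from those of their partners. The same holds for the overlapping genes ASB3 and GPR75-ASB3, and for members of near-identical families such as FAM25A, the metallothioneins and the histones.

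The analysis used values as deposited, on the scale log2(FPKM + 1), and kept the 11477 genes with a mean of at least 1 FPKM over the 18 libraries. Fold changes on this scale understate the change of low genes. One limma model (version 3.58.1, R 4.3.3) with a mean-variance trend was fitted to the 6 group means over all 18 libraries, with 12 residual degrees of freedom. The 9 contrasts were each drug group against DMSO, 24 h against 6 h in each line, the difference between the lines of each drug effect (an interaction), and PATU-8902 against PATU-8988T in DMSO. All p-values of genes are 2-sided, with Benjamini-Hochberg adjustment over the kept genes within a contrast, and a gene passed at an adjusted p below 0.05. Errors of log2 fold changes are standard errors of this model (SE) and errors of FPKM are standard deviations (SD), with 3 libraries per group.

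Gene lists were fixed before the data were examined: 41 lists of pathways, target genes and markers of other cell types. The 32 lists with at least 5 kept members were tested with limma's camera at the preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation. Library medians were compared with a 2-sided exact permutation test, for which 3 libraries against 3 cannot give a p below 0.1.

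Library medians differed within groups, so the same model was also fitted after median-centring, in which each library was shifted on the log2 scale to a common median. This alternative was listed before the data were examined. Giving its values beside the main ones, and for many named genes in their place, was decided afterwards. Centring removes differences in overall level relative to the spike-ins, and it also shifts genes that lie at the floor. Other alternatives fixed beforehand were a pseudocount of 0.1, no filter, a filter of 5 FPKM, the replicate number as a block, a fit on the compared groups alone, rescaling by the spike-ins and leaving out each library. Cyclic loess, a correction for transcript GC content and the joint removal of PATU-8988T DMSO replicates 2 and 3 were added after seeing the data. Transcript length and GC were medians over the reference transcripts of a symbol and were found for 95.2% of the kept genes.

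Genes are named by a rule set before the data were examined. The DCLK family and related kinases are named in every group. For each drug comparison, up to 10 genes higher and 10 lower are named from those past the threshold with all 3 treated libraries on one side of the 3 DMSO libraries. Where fewer than 5 passed, the 5 smallest unadjusted p are named as not past the threshold. The other contrasts name 5 each way, and members of the fixed lists may be named with their list. The same rule was applied to the centred fit, which was decided after seeing the data. Rows of spike-ins and small RNAs were not ranked. Some genes that met the rule are not reported here, and list counts include them.

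The model was tested on simulated data for the PATU-8902 24 h comparison, with 200 changed genes among 11477 in each of 10 runs. As deposited, it recovered 0 of 670 genes changed 1.5-fold, 23.0% of those changed 2-fold and 96.4% of those changed 3-fold. After centring the shares were 66.1%, 92.7% and 98.2%. Wrong calls made up 4.47% of calls as deposited and 4.68% after centring. A list of 24 genes raised 1.5-fold was called in 10 of 10 runs and an unchanged list in 1 of 10. These list calls used an unadjusted camera p below 0.05 at the preset correlation. Noise was drawn independently for each gene, so these rates do not cover trends shared by genes or correlated lists. Figures were drawn with matplotlib 3.10.9.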

Results

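The series measured which transcripts change when pancreatic cancer cells are exposed to DCLK1-IN-1, an inhibitor of the kinase DCLK1. PATU-8988T and PATU-8902 are established lines of human pancreatic ductal adenocarcinoma. Each line contributed 3 libraries of DMSO-treated cells at 24 h, 3 at 6 h of 2.5 µM inhibitor and 3 at 24 h of inhibitor. Between 10049 and 11423 genes per library reached 1 FPKM. The median FPKM of the 11477 genes tested ranged from 6.12 to 17.4 over the 18 libraries and was 1.97-fold higher in PATU-8988T DMSO replicate 2 than in replicate 1. Pearson's r of log2 values between libraries of a group lay between 0.957 and 0.981.

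**Figure D1:**
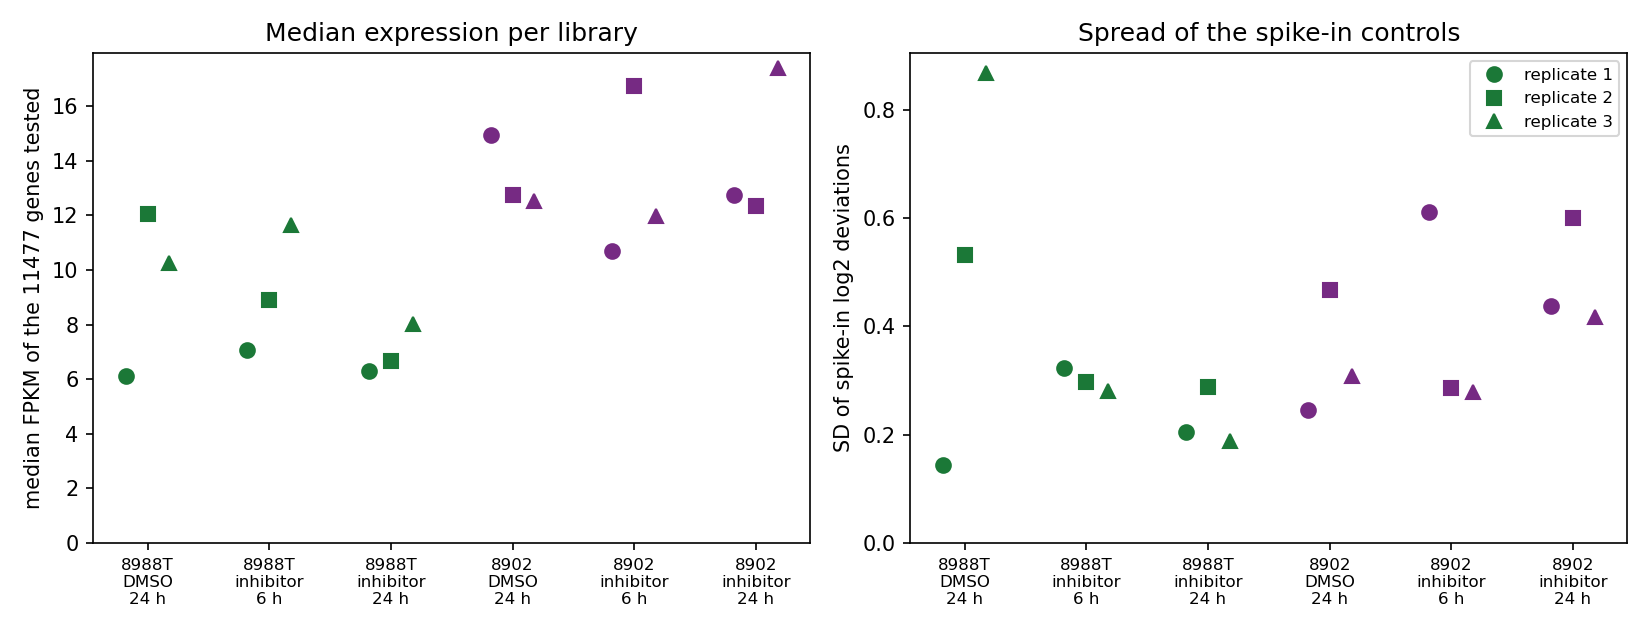
Left, the median FPKM of the genes tested in each library (y axis, linear). Right, the standard deviation of the log2 deviations of 47 spike-in controls from their mean over libraries (y axis, log2 units). The x axis gives the 6 groups of 3 libraries and symbols mark replicate numbers. The median in PATU-8988T DMSO ran from 6.12 to 12.1 FPKM, and the spike-in spread reached 0.869 in replicate 3 of that group.

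The library medians differed between inhibitor and DMSO by amounts that depended on single libraries. In PATU-8988T the mean log2 library median moved by -0.35 at 24 h (exact permutation p = 0.4) and by -0.02 at 6 h (exact permutation p = 0.9). The values in PATU-8902 were 0.06 at 24 h (exact permutation p = 0.9) and -0.04 at 6 h (exact permutation p = 0.8). Each comparison had 3 libraries per group and could not give a p below 0.1. In PATU-8988T at 24 h the value was -0.605 without DMSO replicate 1 and -0.167 without DMSO replicate 2, and at 6 h it ran from -0.271 to 0.167 without the same libraries. In PATU-8902 it ran from -0.220 (without 6 h replicate 2) to 0.0806 (without 6 h replicate 1) at 6 h, and from -0.0846 (without 24 h replicate 3) to 0.146 (without 24 h replicate 2) at 24 h. Because medians varied this much within groups, counts are given as deposited and also relative to the median of each library. Fold changes of many named genes are given on the centred scale only.

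The targeted gene was expressed in both lines and passed the threshold in none of the 4 drug comparisons, as deposited or centred. DCLK1, which encodes a microtubule-associated kinase of the doublecortin family, measured 27.4 ± 7.04 FPKM (SD, n = 3) in PATU-8988T DMSO, 29.2 ± 6.42 at 6 h and 21.2 ± 3.10 at 24 h of inhibitor. In PATU-8902 the corresponding means were 23.7 ± 2.07, 23.8 ± 6.27 and 25.1 ± 5.37 FPKM. The largest difference from DMSO in mean FPKM was the lower DCLK1 value at 24 h in PATU-8988T. Its largest centred log2 change was 0.11 ± 0.06 (SE, adjusted p = 0.249), at 6 h in PATU-8988T. The paralogues DCLK2 and DCLK3 lay at or near the floor in all 18 libraries, with highest values of 0.199 and 0.118 FPKM. DCX, which encodes doublecortin, and LRRK2, a kinase gene linked to Parkinson's disease, did not exceed 0.118 and 0.131 FPKM. Of the other kinases related to the compound's scaffold, MAPK7 (ERK5) averaged 4.36 FPKM in PATU-8988T DMSO and 4.97 in PATU-8902 DMSO. MAPK7 and TNK2 passed the threshold in none of the 4 drug comparisons, as deposited or centred.

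**Figure D2:**
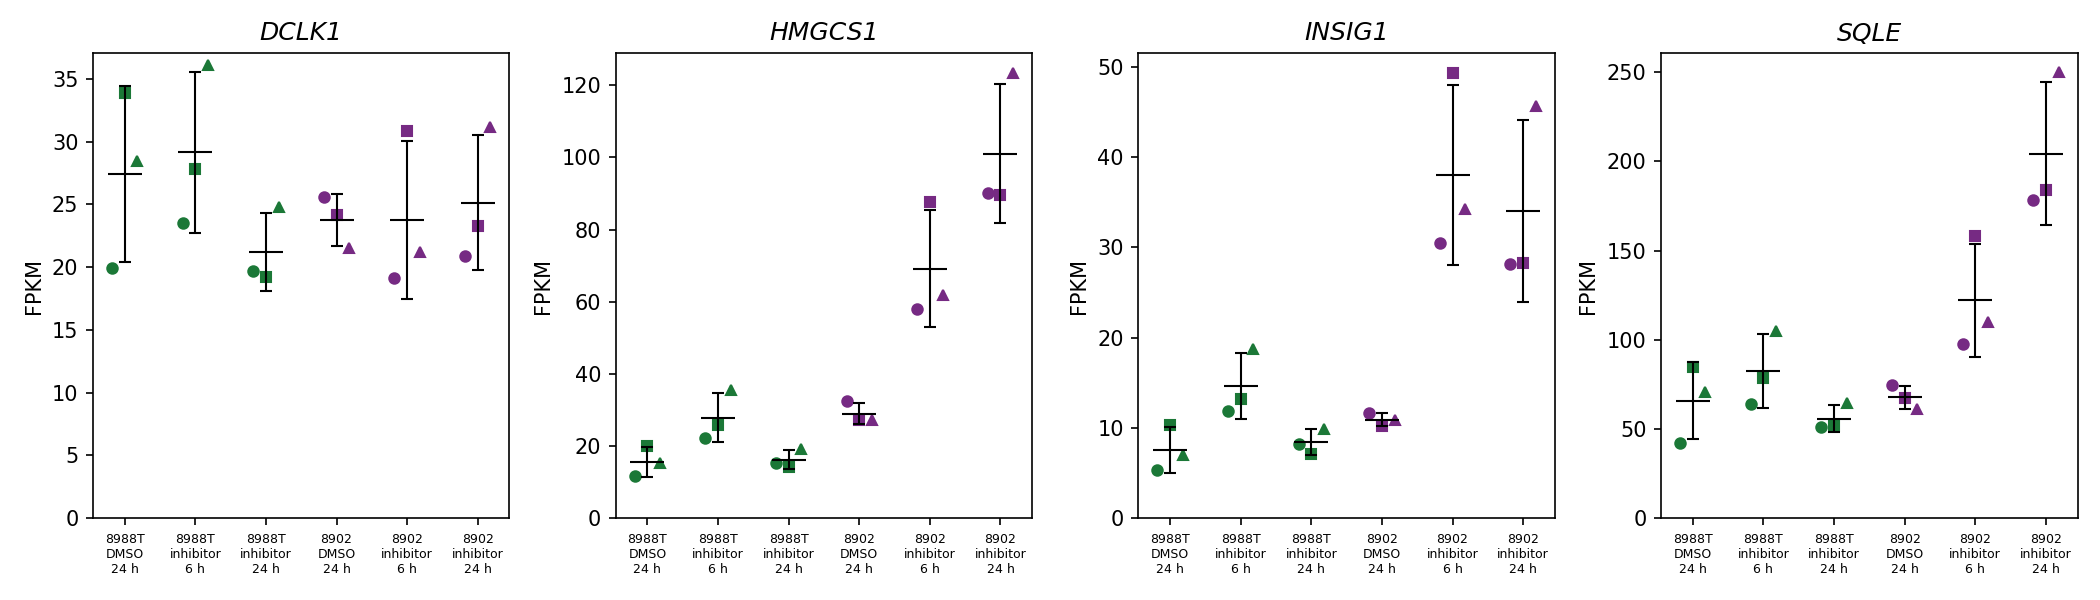
FPKM of DCLK1, HMGCS1, INSIG1 and SQLE (y axes, linear) in each of the 18 libraries (points, symbols by replicate as in the plot of library medians), with group means and standard deviations (black bars, n = 3). DCLK1 means lie between 21.2 and 29.2 FPKM. The HMGCS1 mean in PATU-8902 rises from 29.01 FPKM in DMSO to 101.01 at 24 h of inhibitor.

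In PATU-8902 cells after 24 h of inhibitor, genes of cholesterol synthesis rose together. HMGCS1, which makes the HMG-CoA used for mevalonate, went from 29.01 ± 3.001 to 101.01 ± 19.3 FPKM (SD, n = 3), a 3.23-fold rise on the centred scale (log2 1.69 ± 0.07 SE, adjusted p = 4.39e-10). SQLE, the squalene epoxidase, rose 2.83-fold (adjusted p = 9.38e-11) and HSD17B7, a sterol-ring reductase, 3.22-fold (log2 1.69 ± 0.12). As deposited the log2 changes were 1.75 for HMGCS1 (limma adjusted p = 0.003054), 1.57 for SQLE (adjusted p = 0.02316) and 1.75 for HSD17B7 (adjusted p = 9.08e-04). INSIG1, a sterol-regulated protein that holds the SREBP activators in the endoplasmic reticulum, rose 2.74-fold. Of the 24 members of the cholesterol synthesis list, 21 rose and 0 fell after centring, with a median log2 change of 1.07.

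The remaining named members of that list covered the pathway from mevalonate to sterols. MSMO1 rose by 1.56, IDI1 by 1.40, DHCR7 by 1.33, CYP51A1 by 1.29 and SC5D by 1.16 on the centred log2 scale. STARD4, a carrier of cholesterol between membranes, rose by 1.47. The transcription factor gene SREBF2 rose by 0.83 ± 0.11. SREBF2 and DHCR7 did not pass as deposited. FDPS at 0.63 ± 0.14, EBP at 0.52 ± 0.13 and PMVK at -0.16 ± 0.14 did not pass. Adjusted over the list alone, 23 members passed. The list gave an adjusted p = 2.54e-89 with the preset correlation and an adjusted p = 9.47e-07 with an estimated correlation.

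Fatty acid synthesis genes rose in part in the same cells. After centring, 4 of 12 members passed: ELOVL6 (log2 0.94 ± 0.06) and ACSL3 (0.42 ± 0.06), which elongate and activate fatty acids, SCD (0.92 ± 0.08), the stearoyl-CoA desaturase, and ACSS2 (0.95 ± 0.08), which makes acetyl-CoA from acetate. FASN stood at 0.55 ± 0.13 and ACLY at 0.34 ± 0.11 without passing, and SREBF1 at -0.05 ± 0.09. Over the list alone 9 passed, and the list gave an adjusted p = 3.41e-05 with an estimated correlation. FAM25A fell from 6.42 ± 1.67 to 0.895 ± 1.05 FPKM (log2 -2.15 ± 0.29, adjusted p = 7.41e-04). RNASET2, a lysosomal ribonuclease gene, fell by 0.35 and GPR75-ASB3 by 0.86. RNASET2 passed in 1 of 6 fits that left out a library, GPR75-ASB3 in 0 and, of the cholesterol genes, NSDHL in 2 and MVD in 3.

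As deposited, 13 of 11477 genes passed in this comparison, 12 higher and 1 lower, and 51 passed after centring, 48 higher and 3 lower. The deposited count fell to between 6 (without 24 h replicate 3) and 11 when 1 library was left out, and was 8 without DMSO replicate 2, DMSO replicate 3 or 24 h replicate 1. It was 3 when only the compared groups were fitted and 25 (15 higher, 10 lower) without the expression filter. The centred calls held 11 of the 13 deposited ones. Among the 13 were HMGCS1, HSD17B7, MSMO1, SQLE, STARD4, INSIG1, IDI1, CYP51A1, SC5D and FAM25A, with LIPG (log2 0.92) and HYAL1 (log2 0.86), the last 2 named after their values were seen. As deposited, 10 cholesterol members rose, 20 over the list alone, with a list adjusted p = 0.007172 under an estimated correlation, while the fatty acid list had an adjusted p = 0.969 there. Small downward shifts of oxidative phosphorylation genes (centred median -0.19), cytosolic ribosomal protein genes (-0.22), MYC targets (-0.10), G1/S genes (-0.11) and G2/M genes (-0.07) passed with the preset correlation only. Their adjusted p was 0.703 each with an estimated correlation, and 0 members of these lists passed on their own. Of the 51 calls, 37 passed in each of the 6 fits that left out 1 library of the comparison.

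**Figure D3:**
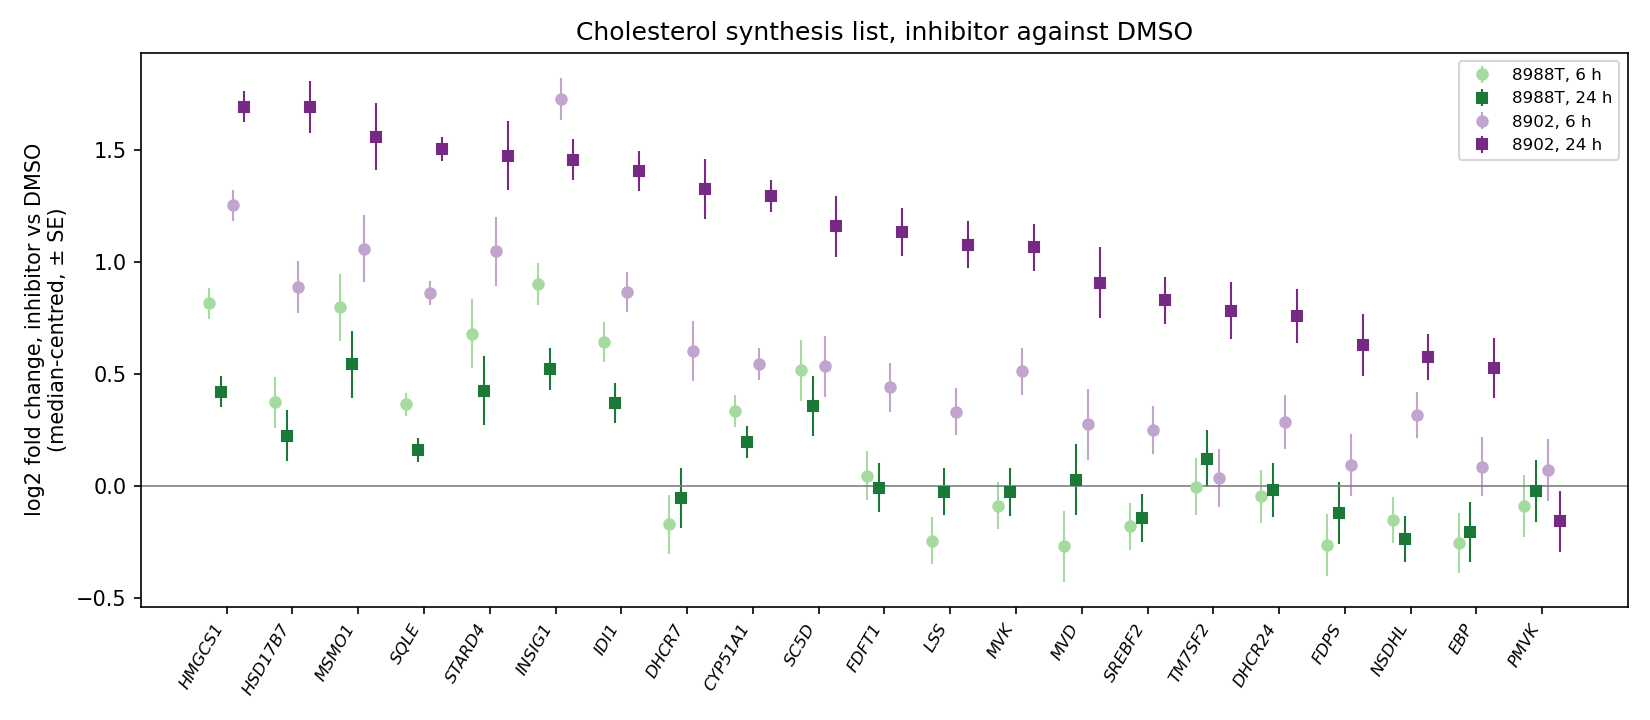
Centred log2 fold changes against DMSO (y axis, with standard errors of the model) of members of the cholesterol synthesis list (x axis), for 6 h (circles) and 24 h (squares) of inhibitor in PATU-8988T (green) and PATU-8902 (purple), 3 libraries per group. In PATU-8902 at 24 h the values run from -0.16 (PMVK) to 1.69 (HMGCS1), and the other genes shown lie above 0.

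The 6 h comparison in PATU-8902 showed the same pathway with smaller changes for most members. Its DMSO cells were taken at 24 h, so effects of the inhibitor and of time cannot be told apart at 6 h. INSIG1 rose 3.31-fold (centred log2 1.73 ± 0.09 SE, adjusted p = 4.08e-08), from 10.9 ± 0.754 to 38.0 ± 9.95 FPKM (SD, n = 3). HMGCS1 rose 2.38-fold (log2 1.25 ± 0.07) and SQLE by 0.86 ± 0.05. IDI1 rose by 0.87, MSMO1 by 1.06, STARD4 by 1.05, HSD17B7 by 0.89 and CYP51A1 by 0.54. In all, 10 of the 24 cholesterol genes rose after centring (19 over the list alone) and 0 fell, with a median of 0.54 and an adjusted p = 1.63e-06 under an estimated correlation.

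Other changes at 6 h in PATU-8902 were few. MYLIP, which encodes a sterol-regulated ubiquitin ligase, fell by 0.78 ± 0.13 (adjusted p = 0.0206, centred), from 7.03 ± 0.741 to 3.59 ± 0.876 FPKM. No single fatty acid synthesis gene passed over all genes, 4 passed over the list alone, and the list as a whole was higher (centred median 0.14, adjusted p = 0.006602 with an estimated correlation). Metallothionein and zinc-response genes were lower as a list (5 members, median -0.38, adjusted p = 0.023 with an estimated correlation), with MT1F at -0.71 ± 0.26 and MT1X at -0.38 ± 0.16, neither past the threshold alone. Interferon-stimulated, TGF-beta, MYC, CLEAR lysosomal and mesenchymal lists passed with the preset correlation, with centred medians of 0.19, -0.12, -0.07, 0.03 and -0.09. With an estimated correlation their adjusted p were 0.253, 0.2215, 0.406, 0.376 and 0.351. As deposited the lysosomal list had a median of -0.02 and a mean of 0.05, and camera placed it above the other genes.

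As deposited, only INSIG1 passed at 6 h (log2 1.68 ± 0.26, adjusted p = 0.0416), beside 79 genes at an unadjusted p below 0.05. The next 4 by p, not past the threshold, were LIPG (0.67 ± 0.12), STARD4 (1.00 ± 0.19), FAM25A (-1.51 ± 0.30) and HMGCS1 (1.21 ± 0.24). After centring 13 genes passed, 12 higher and 1 lower. As deposited the cholesterol list held with an estimated correlation (adjusted p = 0.0204), while the fatty acid list had an adjusted p = 0.991 and the metallothionein list an adjusted p = 0.588. INSIG1 as deposited passed in 0 of the 6 fits that left out a library. MYLIP passed in 1 of 6 fits that left out a library.

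Between 6 h and 24 h of inhibitor in PATU-8902, genes of sterol and fatty acid synthesis rose further. Among them HSD17B7, HMGCS1, SQLE, CYP51A1 and IDI1 had passed at 6 h already. No DMSO was taken at 6 h, so effects of the inhibitor and of time itself cannot be told apart here. C14orf1 (ERG28, a scaffold of sterol-synthesising enzymes) rose by 0.99 ± 0.07, HSD17B7 by 0.80 ± 0.12, ACAT2 (acetoacetyl-CoA thiolase) by 0.79 ± 0.10, and ELOVL6 by 0.78 ± 0.06 (centred log2, SE, 3 libraries per group). The glycolytic aldolase gene ALDOC rose by 0.84 ± 0.13. TXNIP, an inhibitor of thioredoxin, fell by 0.59 ± 0.07 after a rise of 0.42 ± 0.07 at 6 h against DMSO (past the threshold in 2 of 6 fits that left out a library), and DALRD3, NINJ1 and GPR75-ASB3 fell by 0.62, 0.50 and 0.97. Of the 24 cholesterol genes, 11 rose and 0 fell (adjusted p = 2.61e-04 with an estimated correlation), and 3 of 12 fatty acid genes rose, SCD, ACSS2 and ELOVL6 (adjusted p = 2.85e-04 with an estimated correlation). As deposited both list calls were lost with an estimated correlation (adjusted p = 0.8112 and adjusted p = 0.9852). INSIG1 stood at -0.27 ± 0.09 without passing. Ribosomal protein and oxidative phosphorylation lists were lower at the preset correlation (centred medians -0.17 and -0.18), with an adjusted p = 0.840 each under an estimated one. After centring 28 genes passed, 24 higher and 4 lower, and as deposited 0 passed, with 197 at an unadjusted p below 0.05. Without 6 h replicate 3, 17 passed after centring. DALRD3 and NINJ1 passed in 0 of 6 fits that left out a library, GPR75-ASB3 in 2 and ALDOC in 4. Of the cholesterol genes, DHCR7, MVK and SREBF2 passed in 1 of 6, IDI1 and TM7SF2 in 2 and FDFT1 in 3. These cholesterol genes also did not pass after centring with the replicate number as a block.

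In PATU-8988T cells at 6 h of inhibitor, a smaller group of sterol genes was higher than in DMSO after centring. The DMSO cells were taken at 24 h, so effects of the inhibitor and of time cannot be told apart here. INSIG1 rose 1.87-fold (log2 0.90 ± 0.09 SE, adjusted p = 3.14e-04) and HMGCS1 1.76-fold (0.81 ± 0.07), followed by IDI1 (0.64 ± 0.09), SQLE (0.36 ± 0.05) and PANK3 (0.36 ± 0.06), a pantothenate kinase that starts coenzyme A synthesis. IFITM1, an interferon-induced membrane protein gene, fell by 1.37 ± 0.18, from 2.76 ± 1.40 to 0.438 ± 0.629 FPKM (SD, n = 3). The zinc transporter gene SLC39A4 fell by 0.63 and HBEGF, an EGF receptor ligand gene, by 0.54. Of the 24 cholesterol genes, 5 rose (11 over the list alone), 0 fell, and LSS stood at -0.25 ± 0.11 and FDPS at -0.26 ± 0.14 without passing. The list median was 0.03, with an adjusted p = 0.00102 at the preset correlation and an adjusted p = 0.779 with an estimated one. Ribosomal protein, SRF/MRTF actin, oxidative phosphorylation and MYC lists were lower at the preset correlation (centred medians -0.34, -0.28, -0.23 and -0.14), each with an adjusted p = 0.779 under an estimated correlation.

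As deposited, 0 genes passed in limma at 6 h in PATU-8988T, beside 287 at an unadjusted p below 0.05. After centring 9 passed, beside 3390 at an unadjusted p below 0.05. The 5 smallest p as deposited, not past the threshold, belonged to ASB3 (1.00 ± 0.21), TP53INP1 (0.56 ± 0.13), IFITM1 (-1.39 ± 0.33), GCSHP3 (0.82 ± 0.20) and BLOC1S5 (1.60 ± 0.39). The centred count was 4884 without DMSO replicate 1 and 4 without 6 h replicate 3. INSIG1, HMGCS1 and IFITM1 passed in all 6 fits that left out a library, IDI1 in 5, SQLE in 4, PANK3 and HBEGF in 2 and SLC39A4 in 1. After GC correction 6 of the 9 calls remained, without SQLE, PANK3 and SLC39A4. With DMSO replicates 2 and 3 left out together, which leaves 1 DMSO library, 4 remained, without IFITM1, IDI1, PANK3, SLC39A4 and HBEGF.

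After 24 h of inhibitor in PATU-8988T no gene passed, as deposited or centred. Among the smallest p after centring were those of HMGCS1 (log2 0.42 ± 0.07 SE, adjusted p = 0.206), INSIG1 (0.52 ± 0.09), ZNF337-AS1 (0.53 ± 0.11) and the glycyl-tRNA synthetase gene GARS (-0.25 ± 0.05), with 3 libraries per group. As deposited the smallest belonged to the stress-response gene ATF3 (-0.75 ± 0.20), HIST1H4C (-1.25 ± 0.35), GAL (-0.69 ± 0.20), the cell-cycle inhibitor gene CDKN1A (-0.72 ± 0.21) and TCTEX1D2 (-0.82 ± 0.24). Of the 24 cholesterol genes, 0 passed over all genes and 9 over the list alone, with a centred median of 0.14 and an adjusted p = 0.701 under an estimated correlation. As deposited that list had a median and a mean of -0.21 each, while camera placed it above the other genes, whose median was -0.35.

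Several other lists passed at 24 h in PATU-8988T with the preset correlation only. With an estimated correlation the adjusted p was 0.456 for the ATF4 list, 0.725 for G1/S and 0.701 for ribosomal protein, SRF/MRTF actin, oxidative phosphorylation, MYC, unfolded protein response and tubulin genes. After centring, ribosomal protein genes had a median of -0.36 with 0 of 27 members above 0, SRF/MRTF actin genes such as TAGLN (-0.43 ± 0.14) and ACTB (-0.36 ± 0.16) a median of -0.25, and ATF4 stress genes such as ATF4 (-0.39 ± 0.14) and CARS (-0.34 ± 0.10) a median of -0.23. Lists of oxidative phosphorylation, MYC, G1/S, unfolded protein response and tubulin genes had medians of -0.24, -0.13, -0.11, -0.11 and -0.15. No member of these lists passed over all genes. Epithelial marker genes had a median of 0.31 after centring and -0.04 as deposited (adjusted p = 0.728 and adjusted p = 0.989 with an estimated correlation), and most of them lay near the floor in this line.

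The count at 24 h in PATU-8988T rested on the DMSO libraries. Leaving out DMSO replicate 1 gave 6514 genes as deposited and 4680 after centring, and the full fit had 687 genes at an unadjusted p below 0.05 as deposited and 1923 after centring. Cyclic loess called 1 gene. Between 6 h and 24 h in this line 0 genes passed in limma under either scaling, with 665 and 544 genes at an unadjusted p below 0.05. G2/M genes had a centred median of -0.12 at 24 h against 6 h (adjusted p = 0.325 with an estimated correlation), and p53 targets had a median of -0.43 as deposited and -0.10 after centring (adjusted p = 0.980 and adjusted p = 0.399 with an estimated correlation). Interferon-stimulated, NF-kB, epithelial, WNT, immediate early, heat shock and cholesterol genes had centred medians of 0.17, 0.26, 0.29, 0.12, 0.14, -0.11 and -0.07, past the threshold with the preset correlation only. With an estimated one their adjusted p were 0.399, 0.399, 0.593, 0.274, 0.325, 0.593 and 0.399. As deposited the interferon-stimulated, NF-kB and epithelial lists had medians below 0 (-0.16, -0.08 and -0.04) while camera placed them above the other genes.

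The drug effect at 24 h differed between the lines for sterol genes. After centring, HSD17B7 changed by 1.47 ± 0.16 more in PATU-8902 than in PATU-8988T (log2, SE of the interaction, adjusted p = 2.60e-04), DHCR7 by 1.38 ± 0.19, SQLE by 1.35 ± 0.07, HMGCS1 by 1.27 ± 0.10 and FDFT1 by 1.14 ± 0.15. FAM25A changed by -2.56 ± 0.41, from a level near the floor in PATU-8988T DMSO (0.087 ± 0.013 FPKM), and did not pass with a pseudocount of 0.1. Of the 24 cholesterol genes, 13 differed toward PATU-8902 and 0 the other way (median 0.95, adjusted p = 4.50e-06 with an estimated correlation), as did 3 of 12 fatty acid genes, ELOVL6, ACSS2 and SCD (adjusted p = 3.38e-04 with an estimated correlation). SCD and the cholesterol gene NSDHL each passed in 2 of 12 fits that left out a library. Centred, 26 genes passed, 25 of them higher in PATU-8902. With PATU-8988T DMSO replicates 2 and 3 left out together, 17 of these remained, and FAM25A, SREBF2, ACAT2, NSDHL and SCD were among those lost.

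As deposited, HSD17B7 alone passed (1.88 ± 0.29, adjusted p = 0.0433), and the cholesterol list had a median of 1.37 with an adjusted p = 0.0738 under an estimated correlation, against an adjusted p = 0.9987 for the fatty acid list. Leaving out PATU-8988T DMSO replicate 1 gave 14 genes as deposited and 636 after centring. HSD17B7 as deposited passed in 2 of the 12 fits that left out a library, without replicate 1 of the DMSO libraries of either line. At 6 h no gene differed between the lines in limma, with 99 at an unadjusted p below 0.05 as deposited and 1385 after centring. The cholesterol list differed at 6 h after centring (median 0.41, 12 members over the list alone, adjusted p = 0.0154 with an estimated correlation) and had an adjusted p = 0.933 as deposited.

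Of the genes called higher after centring in PATU-8902, 11 were called at both times, among them CYP51A1, HMGCS1, HSD17B7, IDI1, INSIG1, LPIN1, MSMO1, SQLE and STARD4. There were 12 at 6 h and 48 at 24 h, and independent lists of these sizes would share 0.05 genes. Part of the overlap may come from the shared DMSO libraries, which are too few to split. The log2 fold changes of 6 h and 24 h had a covariance of 0.0485 across 11477 genes in PATU-8902, between 0.0394 in the centred simulation of unchanged groups and 0.0625 in the deposited one. In PATU-8988T it was 0.0764, above 0.0393 and 0.0637. The observed covariance is the same under both scalings, while the deposited simulation counts shifts of whole libraries as noise of single genes. Both simulations used a spread pooled over the 6 groups, so these values cannot decide on a shared effect. Calls could not be shared between the lines at 24 h, since 0 genes passed in PATU-8988T. The fold changes of the lines at 24 h had a Spearman rho of 0.40 and a Pearson r of 0.15 across genes, which are not independent replicates.

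In DMSO the lines differed in many genes and in cell-type character. PATU-8902 expressed epithelial keratins that lay near the floor in PATU-8988T: KRT19 at 458.5 ± 91.8 FPKM against 0.109 ± 0.036 and KRT7 at 470.5 ± 111.9 against 0.182 ± 0.010 (SD, n = 3). EMP1, an epithelial membrane protein gene, measured 2194 ± 359.6 FPKM against 0.567 ± 0.233, the calcium-binding protein gene CALB1 803.7 ± 56.9 against 0.109 ± 0.043, and the long non-coding RNA UCA1 694.2 ± 76.2 against 0.118 ± 0.039. PATU-8988T in turn expressed the collagen lysyl hydroxylase gene PLOD2 at 216.7 ± 46.7 FPKM against 0.147 ± 0.035 and the serine synthesis gene PSAT1 at 197.7 ± 49.9 against 0.153 ± 0.046. TUBB6, AKR1B1 and DMKN were also lower in PATU-8902, with centred log2 differences of -7.20, -7.01 and -6.92.

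The marker lists followed the same division of the lines. Of 15 epithelial markers, 14 were higher in PATU-8902 under both scalings, CDH1 (E-cadherin) by 5.89 ± 0.16 and EPCAM by 5.18 ± 0.10 (centred log2, SE), while OCLN stood at -0.34 after centring and 0.16 as deposited. The 15 interferon-stimulated genes kept, of 20 in the list, were higher, IFIT2 by 4.81 and IFIT3 by 4.83. The filter favours such a result, since 17 of the 20 reached 1 FPKM in PATU-8902 and 7 in PATU-8988T. Among mesenchymal markers VIM (vimentin), CDH2, ZEB1 and FN1 were lower, at -5.44, -2.997, -2.89 and -2.50, and SNAI2 was higher by 2.40. Of 15 YAP/TAZ targets, 13 were lower after centring (9 as deposited), with CTGF at -5.60 and CYR61 at -4.69, and 2 higher, F3 and NT5E. NRF2 targets were lower for 11 of 13 genes (8 as deposited), with HMOX1 at -5.11, and ATF4 stress genes for 13 of 19 (9 as deposited), with PHGDH at -5.86. Basal-like subtype genes were higher for 6 of the 7 kept of 18, VGLL1 by 4.31, with the same limit (7 and 3 of the 18 reached 1 FPKM). CLEAR lysosomal genes were lower for 14 of 21 (6 as deposited), and SRF/MRTF actin genes for 11 of 16 (7 as deposited). With an estimated correlation no list passed, the adjusted p being 0.2205 for epithelial, 0.186 for interferon and 0.193 for YAP/TAZ genes after centring.

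As deposited, 6224 genes differed between the lines in DMSO, 4800 higher and 1424 lower in PATU-8902, a share of 77.1% higher. After centring 8284 differed, 3947 higher and 4337 lower, a share of 47.6%, with 5346 of the deposited calls among them. Centring shifted each gene by the difference in mean library median between the lines. These medians were 3.84 in PATU-8902 DMSO and 3.34 in PATU-8988T DMSO (log2 scale). Directions of small differences therefore depend on the scaling used.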

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

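Several of the tests below were chosen only after the result was seen. These were the spike-in ratio, the GC correction and the comparison of replicate 1 with 6 h and 24 h libraries. The centred median, the matched random lists, the leave-one-out median and the sorting of splits by line were also chosen afterwards.

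The sterol response at 24 h was larger in PATU-8902 than in PATU-8988T. DCLK1 had similar FPKM in DMSO in both lines as deposited. The mean of the library median FPKM in DMSO was 13.4 in PATU-8902 and 9.47 in PATU-8988T. Relative to the library median, DCLK1 was therefore lower in PATU-8902. As deposited, HSD17B7 differed by 1.88 on the log2 scale and passed in 2 of 12 fits that left out a library. After centring the differences were 1.47 for HSD17B7, 1.38 for DHCR7, 1.35 for SQLE, 1.27 for HMGCS1, 1.14 for FDFT1, 1.10 for LSS, 1.10 for CYP51A1, 1.09 for MVK, 1.07 for C14orf1 and 1.04 for IDI1. They were 1.01 for ACSS2, 0.97 for SREBF2, 0.94 for ACAT2, 0.94 for INSIG1, 0.88 for ELOVL6, 0.81 for NSDHL, 0.57 for SCD and -2.56 for FAM25A, with NSDHL and SCD each past the threshold in 2 of 12 such fits. With PATU-8988T DMSO replicates 2 and 3 left out together 17 of the 26 centred calls remained, and SREBF2, ACAT2, NSDHL, SCD and FAM25A were among those lost. The cholesterol list differed by a median of 0.41 at 6 h and 0.95 at 24 h, and the fatty acid list by 0.22 at 24 h.

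For the rise of cholesterol genes at 24 h in PATU-8902, library scaling was set against the centred median of 1.074. Mean library medians of inhibitor and DMSO differed by 0.06 (log2), so centring could shift the list only by that amount. Length and GC were set against 10000 random lists matched in expression, length and GC, of which 0.00% reached the value and the highest gave 0.062. A single deviating library was set against the lowest leave-one-out median of 1.051. None of these accounts for the rise. Lysosomal stress from a basic compound, which could raise sterol genes by trapping cholesterol, was tested on the lysosomal list (camera adjusted p = 0.8372) and cannot be told from the data.

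In PATU-8988T DMSO, replicates 2 and 3 stood above replicate 1 at most genes. The smaller of their spike-in SDs (replicate 2) was 1.646 times the largest of the other 7 libraries of the line, although PATU-8902 6 h replicate 1 (0.611) and 24 h replicate 2 (0.600) exceeded it. The difference from replicate 1 had a Spearman rho of 0.470 with GC content, 0.477 with expression level and -0.111 with length. GC trends of single libraries, taken against the mean of the line, had rho of -0.257, 0.427 and 0.607 in DMSO. The values were -0.533, -0.683 and -0.476 at 6 h, and -0.137, 0.430 and -0.497 at 24 h. Trends taken against a common mean are not independent between groups. They cannot tell a trend with the treatment from that of single libraries, and a technical origin is left open. GC was not the whole cause, since 3175 genes still passed at 24 h without replicate 1 after GC correction. A 6 h library under the wrong label is unlikely, as sterol genes of replicate 1 lay 0.374 below the lowest 6 h library. For a 24 h library the distance was 0.104 and the test cannot tell. The mean centred deviation of these genes was -0.163 in replicate 1, -0.332 in replicate 2 and -0.355 in replicate 3. It was -0.059 in the lowest 24 h library, so replicate 1 lay nearer to that library than to replicates 2 and 3.

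MYLIP is a target of the sterol-sensing LXR receptors, so its fall at 6 h might reflect lower LXR activity. Of the other measured LXR targets, the 5 left after setting aside SCD (0.26) and SREBF1 (-0.12), which SREBP proteins also regulate, had a median of -0.09 (2 above 0), and 2.4% of random lists were as low. This met the bound set for lower LXR activity (5%), but members went both ways. The median was smaller in size than their median SE of 0.16. The DMSO cells were also taken at 24 h and not at 6 h, so the question is left open.

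Swapping group labels gave too few splits (10) for a share under 0.05 in each single comparison. As deposited, the real counts and the highest other counts were 0 and 7425 for PATU-8988T at 6 h, 0 and 7403 at 24 h, and 0 and 2 for 24 h against 6 h. Here 10 of the 10 splits reached the real count. Any split reaches a count of 0, so such tallies say nothing about chance. In PATU-8902 they were 1 and 0 at 6 h, 13 and 1 at 24 h, and 0 and 1 for 24 h against 6 h, and 6224 and 1 between the lines in DMSO. After centring they were 9 and 2891 and then 0 and 3208 in PATU-8988T (2 and 10 splits), and 13 and 1, 51 and 0, and 28 and 1 in PATU-8902 (1 split each). For the line difference 100 splits were made. At 6 h 100 of them reached the deposited count of 0, as any split must, and the highest was 7918. At 24 h 27 of them reached 1, the highest being 7671. After centring 9 of 100 reached the 26 genes at 24 h, the highest being 3281, so chance is not excluded, and this tally does not speak for chance either. Of these 9 splits, the real one included, 8 kept the grouping of PATU-8902 as labelled and so its real effect, and 1 of the 79 splits that broke the grouping of both lines reached 26. Splits calling this many genes point to a structure of the samples. In PATU-8988T the highest split against DMSO, at 6 h and at 24 h, placed DMSO replicate 1 opposite replicates 2 and 3. As deposited, the other splits with that DMSO grouping called 0 and 1 genes at 6 h, and 3 and 0 at 24 h. Leaving out replicate 1 gave 6514 genes at 24 h as deposited. Which libraries carried the line-difference splits was not tested.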

How the results depend on the processing

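Values are given in the order PATU-8988T 6 h, 24 h, then PATU-8902 6 h, 24 h, unless named, and the cause was not tested. Without a filter the gene counts were 2, 3, 7 and 25 (15 higher, 10 lower), 13 and 11 for 24 h against 6 h in PATU-8988T and PATU-8902, and 2 for the line difference at 24 h. The list counts were 6 and 3 in PATU-8988T, the calls shared by both times in PATU-8902 were 4, and the median change reversed to 0.0007 at 6 h in PATU-8988T and to 0.0262 and -0.0154 in PATU-8902. A filter of 5 FPKM gave 1 gene at 6 h in PATU-8988T and 0 for the line difference at 24 h, as did a pseudocount of 0.1 for the latter (0). A fit on the compared groups alone gave 5, 4, 0 and 3 genes, 29 for 24 h against 6 h in PATU-8988T, 1 for the line difference at 6 h, 2 lists at 24 h in PATU-8988T and 0 shared calls in PATU-8902. Centring gave 9, 0, 13 and 51 genes, 28 for 24 h against 6 h in PATU-8902, 26 for the line difference at 24 h, 5, 10 and 7 lists (the last at 24 h in PATU-8902) and 11 shared calls. The difference of OCLN between the lines in DMSO reversed to -0.340 after centring. Cyclic loess gave 15, 1, 20 and 62 genes and 32 for the line difference at 24 h. Centring with GC correction gave 9, 0, 20 and 61 genes, 37 for 24 h against 6 h in PATU-8902 and 2 and 33 for the line difference at 6 h and 24 h. Removing PATU-8988T DMSO replicates 2 and 3 together left 1 library in that group, so its spread came from the other groups, and gave 4 and 3 genes in PATU-8988T as deposited and 3 at 24 h after centring. With an estimated correlation 0, 0, 1 and 1 lists passed. The replicate number as a block gave 0 genes and 0 shared calls at 6 h in PATU-8902 and, after centring, 5 genes at 6 h in PATU-8988T and 17 for 24 h against 6 h in PATU-8902. Numbers showed no clear pairing of samples. Libraries of the same number had r over 0.1 in 3 of 9 pairs in PATU-8988T and 0 of 9 in PATU-8902. Pairs of different number did so in 3 of 18 and 6 of 18. With 3 libraries per group this cannot exclude pairing. Rescaling by spike-ins gave 6138 genes between the lines in DMSO (6224 without it) and left the other gene and list counts unchanged. The deposited values were already level on the spike-ins, so this rescaling could change little. Leaving out single libraries gave 0 to 3, 0 to 6514, 0 to 3 and 6 to 11 genes, 0 to 1 and 0 to 0 for 24 h against 6 h, 0 to 2 and 0 to 14 for the line difference, and 5304 to 6760 between the lines in DMSO. Lists ranged 2 to 6, 4 to 6, 4 to 8 and 2 to 7, and the median change -0.271 to 0.167, -0.605 to -0.167, -0.220 to 0.0806 and -0.0846 to 0.146. Shared calls ranged 0 to 3 in each line and 0 to 0 between lines. After centring the gene counts ranged 4 to 4884, 0 to 4680, 11 to 15 and 40 to 46, 17 to 23 for 24 h against 6 h in PATU-8902 and 21 to 636 for the line difference at 24 h.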

Other observations

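Single genes outside the cholesterol and fatty acid lists also rose at 24 h in PATU-8902 after centring. Those below were picked after their values were seen and were not tested as a group. C14orf1 (ERG28) rose by 1.07 ± 0.07 (log2, SE, 3 libraries per group, adjusted p = 2.68e-07), ACAT2 by 0.96 ± 0.10 and TMEM97, a sterol-regulated membrane protein gene, by 0.48 ± 0.06. IDH1, which makes cytosolic NADPH, rose by 0.70 ± 0.05, RDH11 by 0.55 ± 0.05, ACSL4 by 0.82 ± 0.10, LPIN1 by 0.49 ± 0.07 and MMAB, which shares its promoter region with MVK, by 0.77 ± 0.09. LIPA, the lysosomal cholesterol esterase gene, rose by 0.38 ± 0.07 and passed in 1 of 6 fits that left out a library. None of these passed as deposited.

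In the line difference at 24 h, IDH1 (0.61), RDH11 (0.54), TMEM97 (0.47) and MMAB (0.65) also differed toward PATU-8902 after centring. TMEM97 passed in 11 of 12 fits that left out a library and MMAB in 3 of 12 (highest adjusted p = 0.1515).

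Single libraries held extreme values for small RNAs, which a polyadenylated library measures poorly. In 59 of 26249 genes the highest library exceeded the second highest more than 20-fold at 10 FPKM or more, and 55 of these had names of microRNA, snoRNA, scaRNA or RNU genes. VTRNA1-2, SNAR-G2 and RNVU1-8, also small RNAs, were among the remaining 4. SNORD65 read 29011 FPKM in PATU-8902 DMSO replicate 2 against 0.120 in the next library, and SNORD28 read 3562 in PATU-8902 6 h replicate 3. MIR6739 read 2811 in PATU-8988T DMSO replicate 1.

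Hypothesis: the compound may lower sterol at the endoplasmic reticulum in PATU-8902 and release SREBP2, since the cholesterol genes rose by a median of 1.074 that length and GC did not account for. The test would be to measure sterol levels and processed SREBP2 with and without added cholesterol, beside an inactive analogue and cells without DCLK1. Whether DCLK1 itself is involved is open in these data, because no group lacked the kinase.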
